A study of Mus musculus with 9 samples.

How the data were processed

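Total RNA of 9 mouse oral tumors was purified with a column kit, turned into biotin-labelled cRNA and hybridised to Affymetrix arrays, per the labels' protocols. The deposited table holds 1 linear signal intensity per probe set and array, with values from 1 to 24545. Per the submitters' processing notes the authors used MAS5. Its version, the scaling and any later step are not given in the sources used here. The deposited intensities were already close in scale, since the mean of each array without the highest and lowest 2% of values was 265 to 275.

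The table has 45101 probe sets, of which 64 are controls. Of the other 45037, 34945 had 1 gene symbol in the platform's annotation, 932 had several and 9160 had none. Those with several or none were not tested. By gene identifier 34754 of the named probe sets matched the reference table of mouse genes (assembly GRCm38.p6), which changed 0 symbols and was used only for names. No genome coordinates are given because the build behind the probe sets is not given in the sources used here. The targeted gene and some other genes fixed in advance are not reported here, so the labels were not checked against the targeted gene.

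Values below the 20th percentile of all values (52.6 signal units) were raised to it, and log2 was taken with no further normalization. Each gene was represented by its probe set with the highest mean, and genes under the median of all non-control probe sets (113 signal units) were left out, which left 12167 of 18193 genes. Fold changes are on this floored log2 scale, where 0.0758% of the tested values lay at the floor. A linear model with a mean per group was fitted to all 9 arrays, so that the groups share one estimate of the spread, with limma 3.58.1 (R 4.3.3), lmFit and eBayes with a variance trend. P-values are two-sided and Benjamini-Hochberg adjusted over the genes tested, with a threshold of 0.05. The 4 comparisons were each mutant group against p53-/-, the mutant groups against each other, and the mean of both against p53-/-.

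For gene sets, 29 lists of pathway genes and of markers of epithelium, stroma, muscle, gland, fat, nerve and immune cells were written before the data were examined, and 28 with at least 5 tested genes were used. The remaining list, of sex-linked genes, had 3 tested genes and was not tested. The test was limma's camera with a preset inter-gene correlation of 0.01 and the same variance trend, adjusted over lists within a comparison, with camera with an estimated correlation and fry beside it. Members were also adjusted over the list alone. Means of lists per array and RNA integrity ratios were compared by exact permutation tests, two-sided, where 3 arrays against 3 cannot give a p under 0.1 and 6 against 3 none under 0.0238.

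The genes to be named were set by rule before the data were examined. They were a few genes fixed in advance (Cdkn1a, Mdm2, Ccng1, Ccnd1 and Mki67 among them), in each comparison and direction the 5 genes with the smallest p where fewer passed the threshold, and up to 4 members with the smallest p of each list called or discussed. Genes with the opposite sign on another probe set are named as such. No pair of arrays held identical values in over 50% of the probe sets, and the root mean square log2 difference between arrays was 0.283 to 0.545.

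The fits were tested on simulated data. In 20 simulated sets 200 of 12167 genes were changed, and all genes varied independently. Of genes changed 2-fold 80.7% and of those changed 4-fold 97.8% were called in the comparison of p53R172H/- with p53-/- tumors, with 4.80% of calls false. For both mutant groups against p53-/- these were 86.7%, 97.6% and 4.86%. Genes of the real arrays vary together, so these shares may not hold for them. In 100 further sets with no group effect and the arrays' own correlation between genes, the gene test made calls in 2 sets, the preset camera called lists in 100 and 99 sets for these comparisons, and camera with an estimated correlation in 0. Alternatives were other normalizations, floors, filters, choices of probe set, variance models, covariates for muscle content and RNA integrity, the tumor number as a block, and each array left out in turn.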

Results

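Gene expression was measured in 9 oral tumors of mice, each hybridised to 1 Affymetrix expression array. According to the series' title and design text, the tumors were induced by Ras activation together with p53 alterations, and tumors with a mutant p53 were to be set against tumors with p53 deleted. There were 3 groups of 3 tumors. By their labelled genotypes, the p53-/- tumors had lost p53 and the p53R172H/- tumors carried the p53R172H missense allele over a null allele. The p53R172H/+ tumors carried the missense allele over a wild-type allele, and whether they kept the wild-type allele was not checked. All mice were 1 year old. Nothing in the labels says that the tumors of a group came from different animals, so p-values measure the spread between these tumors. The arrays were alike in brightness, with medians of 109 to 123 signal units and 99th percentiles of 5455 to 5726. Pearson's r of log2 signals across genes, which are not independent replicates, was 0.932 to 0.980 between arrays of a group and 0.932 to 0.981 between groups. The number of arrays limits the precision. No gene passed an adjusted p of 0.05 in any of the 4 comparisons with limma, so the single genes below are given as values, and "rose" or "fell" is used only for members of a fixed gene list that passed after adjustment over the list alone.

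The comparison of p53R172H/- with p53-/- tumors asks how tumors with the mutant protein and no wild-type allele differ from tumors without p53. Of 35 measured mitosis genes, 32 were higher on average in the p53R172H/- tumors, and 26 rose when adjusted over the list alone and 0 when adjusted over all genes tested. The median log2 fold change of the list was 0.58 (adjusted p = 0.361 with an estimated correlation). Among them were Nusap1, a spindle protein (2.02-fold higher, log2 fold change 1.01 ± 0.16 SE), Ccnb2, a mitotic cyclin (1.90-fold, 0.93 ± 0.15 SE), Kif20a, a kinesin of cell division (1.85-fold, 0.89 ± 0.16 SE), and Cdc20, an activator of the anaphase-promoting complex (1.45-fold, 0.54 ± 0.09 SE). All 6 measured salivary gland genes were lower on average in the same comparison, without a call (median -0.16, adjusted p = 0.245). Of 19 measured fibroblast and matrix genes, 9 fell when adjusted over the list alone, 0 over all genes, with a list median of -0.60 (adjusted p = 0.677 with an estimated correlation).

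The falling matrix genes included the collagen genes Col6a2 (1.84-fold lower, -0.88 ± 0.19 SE), Col1a1 (1.84-fold lower, -0.88 ± 0.22 SE), Col1a2 (1.68-fold lower, -0.75 ± 0.18 SE) and Col6a1 (1.77-fold lower, -0.83 ± 0.24 SE). The signal of Col1a1 was 3766 ± 662 (SD, n = 3) in p53-/- and 2055 ± 408 (SD, n = 3) in p53R172H/- tumors. The level of this list also varied within the p53-/- group, from a mean log2 signal of 10.08 in tumor 2 to 10.85 in tumor 3. None of the 9 genes passed over the list alone without p53-/- tumor 1, p53-/- tumor 3 or p53R172H/- tumor 2, where Col1a1 was at -0.85, -0.76 and -0.70.

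Of 16 measured Ras and MAPK output genes, 2 rose and 1 fell when adjusted over the list alone, 0 over all genes, and the list's median was 0.30 (adjusted p = 0.611 with an estimated correlation) and 0.18 without p53R172H/- tumor 1. Dusp6, a phosphatase that switches off ERK, was at 244 ± 33.5 signal units (SD, n = 3) in p53-/- tumors and at 863 ± 163 (SD, n = 3) in p53R172H/- tumors, 3.52-fold higher (1.82 ± 0.32 SE). Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, rose 1.54-fold (0.62 ± 0.12 SE). Ereg, which encodes the EGF receptor ligand epiregulin, fell (-0.59 ± 0.15 SE). Of 15 immediate-early genes, 4 rose when adjusted over the list alone, 0 over all genes, with a list median of 0.36 (adjusted p = 0.361 with an estimated correlation). These were Fos (1.90-fold, 0.93 ± 0.24 SE), Dusp1 (0.59 ± 0.18 SE), Zfp36 and Junb. Of 19 hypoxia and glycolysis genes, 18 were higher on average, but none passed when adjusted over the list alone, and the median was 0.17 (adjusted p = 0.361 with an estimated correlation) and 0.28 without p53-/- tumor 3. Vegfa, the angiogenic growth factor, had a log2 fold change of 0.48 ± 0.15 (SE) and Ero1a, an oxidase of the endoplasmic reticulum, of 0.41 ± 0.13 (SE).

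With an estimated correlation, 4 further lists had an adjusted p of 0.677 (p53 targets, NRF2 targets, mevalonate) or 0.699 (DNA replication). Of 32 p53 target genes, 22 were lower on average (median -0.12, and -0.06 without p53R172H/- tumor 1), and only Dcxr, a carbonyl reductase, fell when adjusted over the list alone (1.80-fold, -0.85 ± 0.16 SE). Among the targets fixed in advance, Cdkn1a, the p21 cell cycle inhibitor, had a log2 fold change of -0.21 ± 0.10 (SE) on its brightest probe set and 0.52 on its other one. Mdm2, which encodes the ubiquitin ligase of p53, had 0.02 ± 0.12 (SE) and Ccng1 -0.45 ± 0.18 (SE). Cdkn1a was at -0.31 without p53-/- tumor 1 and Ccng1 at -0.28 without p53-/- tumor 2, and Mdm2 ran from -0.03 to 0.11 with 1 array left out. The NRF2 target list had a median of -0.18 (-0.09 without p53R172H/- tumor 2) with no member passing, and Gsta2, a glutathione transferase, was at -1.04 ± 0.32 (SE) and at -0.66 without p53-/- tumor 2. In the mevalonate and cholesterol synthesis list (median 0.10, and 0.07 without p53R172H/- tumor 3), Cyp51 (0.43 ± 0.10 SE) and Sc5d (0.59 ± 0.16 SE) rose out of 17 genes when adjusted over the list alone, although another probe set of Sc5d was at -0.01. The DNA replication list had a median of 0.10 and no member that passed. Its median was 0.03 without p53R172H/- tumor 1, 0.21 without p53R172H/- tumor 2 and 0.15 without p53-/- tumor 1. Pold1 was at -0.36 ± 0.11 (SE) and Prim1 at 0.30 ± 0.11 (SE), or 0.20 without p53R172H/- tumor 1.

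Skeletal muscle genes had the largest list median of the 28 lists, 1.35 (adjusted p = 0.677 with an estimated correlation), with high levels in 2 of the 3 p53R172H/- tumors. The mean log2 signal of the muscle list was 6.57 in p53R172H/- tumor 1, 10.76 in tumor 2 and 9.68 in tumor 3, against 7.59 to 8.25 in the p53-/- tumors. Myh4, a myosin heavy chain of fast fibres, was at 1850 ± 2070 signal units (SD, n = 3) in p53R172H/- tumors. No muscle gene passed when adjusted over the list alone. Without p53R172H/- tumors 2 and 3, which leaves 1 tumor in the group, the list's median was -1.21, without tumor 2 alone it was 0.38 with the list no longer called (adjusted p = 0.196), without tumor 3 alone 0.85 and without tumor 1 alone 2.80.

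**Figure D1:**
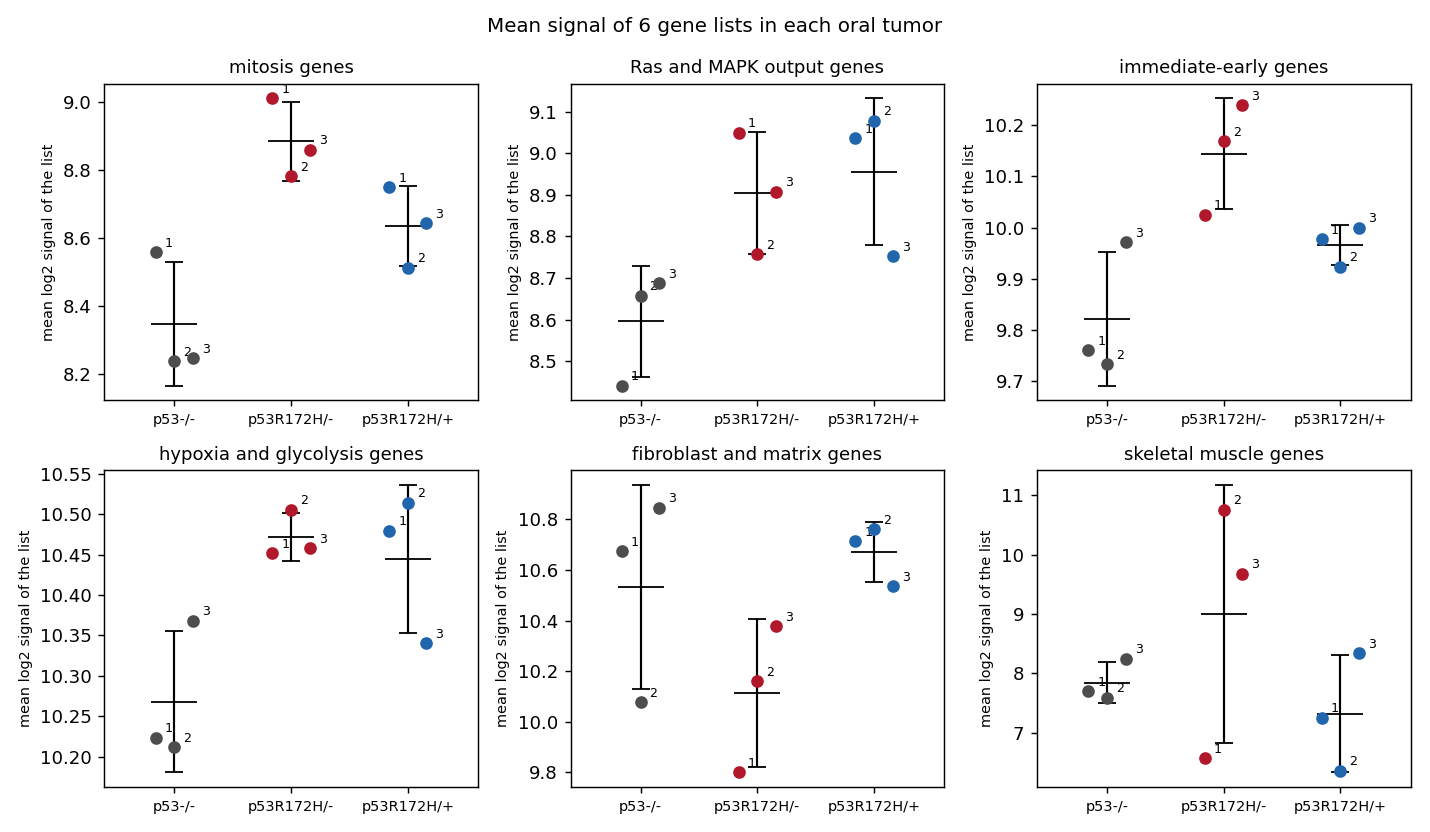
Mean log2 signal of 6 gene lists in each of the 9 tumors, grouped by genotype on the horizontal axis. Each numbered point is a tumor, and the dash and bar give the group's mean and SD (n = 3). The mitosis list lies at 8.24 to 8.56 in p53-/- and at 8.78 to 9.01 in p53R172H/- tumors, while the muscle list spreads from 6.57 to 10.76 within the p53R172H/- group.

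Of the 12167 genes tested in this comparison, 1897 had an unadjusted p under 0.05, 783 higher and 1114 lower, where chance alone gives 608, and the smallest adjusted p was 0.202 (limma). The arrays of the groups did not overlap for 22.9% of genes, against 10% by chance. The genes with the smallest p that were higher were Bnc1, a zinc finger gene of basal keratinocytes (1.90-fold, 0.93 ± 0.14 SE), Pclaf, which encodes a PCNA-binding factor (1.59-fold, 0.67 ± 0.10 SE), Ccnb2, Nusap1 and Cdc20. Those that were lower were Per2, a circadian clock gene (1.60-fold, -0.68 ± 0.11 SE), the collagen gene Col16a1 (1.67-fold, -0.74 ± 0.12 SE), Prrc1 (-0.51 ± 0.08 SE), Selenow, which encodes a selenoprotein (-0.49 ± 0.08 SE), and the kinesin light chain gene Klc3 (-0.52 ± 0.09 SE). None of these passed the adjusted threshold, all with an adjusted p of 0.202. Other probe sets disagreed in sign for Cdc20 (-0.03), Selenow (0.20) and Prrc1 (0.00). The proliferation marker Mki67 was at 0.53 ± 0.15 (SE, adjusted p = 0.220) and Ccnd1, the G1 cyclin D1, at -0.24 ± 0.20 (SE, adjusted p = 0.552), -0.41 without p53R172H/- tumor 1 and -0.10 without p53R172H/- tumor 2.

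With camera's preset correlation, 10 of 28 lists were called, 7 up (mitosis, hypoxia and glycolysis, immediate-early, muscle, Ras and MAPK output, DNA replication, mevalonate) and 3 down (fibroblast and matrix, p53 target, NRF2 target). None was called with an estimated correlation, where the lowest adjusted p was 0.361, for mitosis, immediate-early and hypoxia genes. Nor did any pass by fry, which asks whether a list's genes move one way (lowest adjusted p = 0.0988, mitosis), and 5 lists passed fry's mixed test of change in either direction. In 100 simulated sets with no group effect and the real correlation between genes, the preset setting called at least 1 list in every set, with a median of 6 lists, and called the mitosis list in 56 sets. With each of the 9 arrays left out in turn, 22 of the 26 mitosis genes and 2 of the 3 Ras genes, Dusp6 and Spry2, passed over their list alone every time. None of the 9 fibroblast and matrix, 4 immediate-early and 2 mevalonate genes did so, nor did Dcxr. The call of the Ras list was lost without p53-/- tumor 1 (adjusted p = 0.0531). The call of the mevalonate and cholesterol synthesis genes was lost without p53-/- tumors 1 (adjusted p = 0.0586) or 3 (adjusted p = 0.136) or p53R172H/- tumor 3 (adjusted p = 0.282). The calls of the p53 target genes, NRF2 target genes and DNA replication genes were lost in turn without 4, 6 and 5 different arrays, p53-/- tumor 3 among them each time (adjusted p = 0.213, 0.146 and 0.105 without it).

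**Figure D2:**
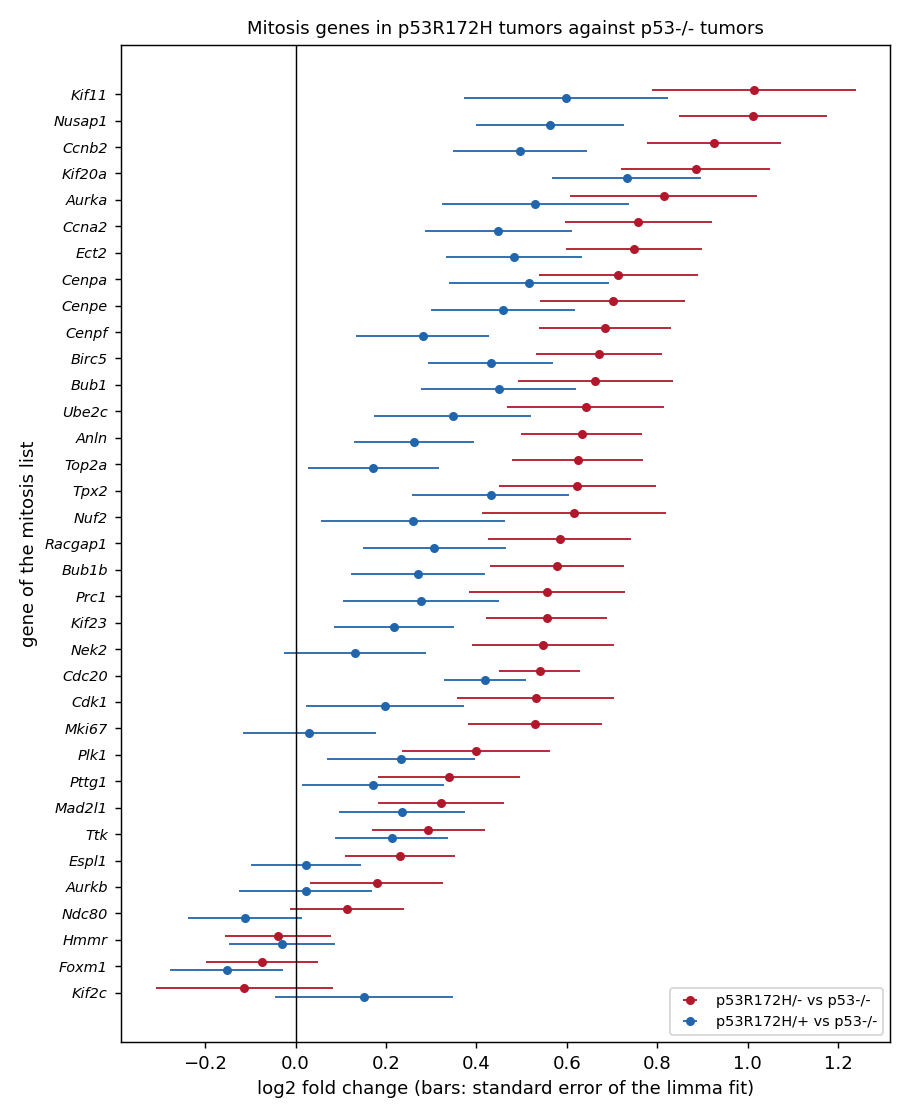
Log2 fold change of the 35 measured mitosis genes against p53-/- tumors, for p53R172H/- tumors in red and p53R172H/+ tumors in blue. Points are limma estimates from 3 tumors per group and bars are standard errors, with Nusap1 at 1.01 and 0.56 and Mki67 at 0.53 and 0.03.

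The comparison of p53R172H/+ with p53-/- tumors asks the same question for mutant tumors with a wild-type allele in their labelled genotype. Of 16 measured Ras and MAPK output genes, 3 rose in the p53R172H/+ tumors when adjusted over the list alone, 0 over all genes. The list's median was 0.32 (adjusted p = 0.434 with an estimated correlation), 0.21 without p53-/- tumor 1 and 0.48 without p53R172H/+ tumor 3. Spry2 rose 1.96-fold (0.97 ± 0.12 SE), from 198 ± 18.9 to 386 ± 9.20 signal units (SD, n = 3 each). Dusp6 rose 3.16-fold (1.66 ± 0.32 SE) with a wide spread between the mutant tumors, 832 ± 390 signal units (SD, n = 3), and Ier3, an early response gene, rose 1.51-fold (0.60 ± 0.13 SE). The 6 salivary gland genes were lower on average here too, without a call (median -0.08, adjusted p = 0.650).

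Of 11 neutrophil genes, 2 rose when adjusted over the list alone, 0 over all genes, namely Il1b, the cytokine interleukin 1 beta (2.76-fold, 1.46 ± 0.36 SE), and Clec4d, a lectin receptor of myeloid cells (2.23-fold, 1.16 ± 0.33 SE), with a list median of 0.25 (adjusted p = 0.434 with an estimated correlation). S100a8, a calcium-binding alarmin held also by the keratin and alarmin list, was at 0.25 ± 0.10 (SE). Of 16 macrophage and monocyte genes, 14 were higher on average and none passed over the list alone, with a median of 0.24 (adjusted p = 0.866 with an estimated correlation). This median was 0.42, 0.03 and 0.37 without p53-/- tumors 1, 2 and 3 in turn and 0.44 without p53R172H/+ tumor 2. Cd14, the lipopolysaccharide co-receptor, was at 0.74 ± 0.19 (SE). Of 35 mitosis genes, Cdc20 (1.34-fold, 0.42 ± 0.09 SE) and Kif20a (1.66-fold, 0.73 ± 0.16 SE) rose when adjusted over the list alone, with a list median of 0.27 (adjusted p = 0.525 with an estimated correlation). Of 15 immediate-early genes, Ier2 (1.47-fold, 0.56 ± 0.13 SE) and Junb (1.41-fold, 0.50 ± 0.13 SE) rose when adjusted over the list alone, with a list median of 0.18 (adjusted p = 0.434 with an estimated correlation) and of 0.10 without p53-/- tumor 2. Hypoxia and glycolysis genes had a median of 0.20 (adjusted p = 0.434 with an estimated correlation), 0.12 without p53-/- tumor 2 and 0.11 without p53R172H/+ tumor 1. No member passed, and Vegfa was at 0.53 ± 0.15 (SE). In the matrix protease and invasion list, which was not called (adjusted p = 0.0657), Mmp13, a collagenase (2.57 ± 0.57 SE), and Adam8, a membrane metalloprotease (0.87 ± 0.22 SE), rose when adjusted over the list alone.

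Muscle genes were lower on average in all 19 members, with a list median of -0.47 and no call (adjusted p = 0.308). Fibroblast and matrix genes had a median of 0.08 without a call (adjusted p = 0.206). p53 target genes were close to even, 15 higher and 17 lower, with a median of -0.02. Cdkn1a was at 0.01 ± 0.10 (SE) on its brightest probe set, while its other one was higher in p53R172H/+ than in p53-/- tumors. Mdm2 was at 0.15 ± 0.12 (SE), Ccng1 at -0.27 ± 0.18 (SE, its 2 other probe sets at 0.02 and 0.07), Ccnd1 at -0.19 ± 0.20 (SE, another probe set at 0.01) and Mki67 at 0.03 ± 0.15 (SE). With 1 array left out, Cdkn1a ran from -0.09 to 0.08, Mdm2 from 0.09 to 0.27, Ccng1 from -0.35 to -0.10, Ccnd1 from -0.34 to -0.00477 and Mki67 from -0.12 to 0.21.

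In this comparison 1259 genes had an unadjusted p under 0.05, 578 higher and 681 lower, against 608 by chance, and the smallest adjusted p was 0.159 (limma), that of Spry2. The arrays did not overlap for 15.9% of genes, against 10% by chance. After Spry2, the smallest p among higher genes belonged to Bnc1 (1.87-fold, 0.90 ± 0.14 SE), the collagen gene Col12a1 (4.73-fold, 2.24 ± 0.35 SE), Prkaa1, which encodes a catalytic subunit of AMPK (1.69-fold, 0.75 ± 0.13 SE), and Mta2, which encodes a chromatin remodelling factor (1.41-fold, 0.49 ± 0.08 SE). Among lower genes it belonged to Per2 (1.62-fold, -0.69 ± 0.11 SE), Cntnap1 (-0.70 ± 0.12 SE), the chemokine receptor gene Ccr6 (-0.66 ± 0.12 SE), Pnpla3, a lipid metabolism gene (-0.84 ± 0.16 SE), and Gltp, a glycolipid transfer gene (-0.34 ± 0.07 SE). None passed the threshold. One other probe set of Col12a1 was at -0.25 and another at 0.82.

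Camera with the preset correlation called 6 lists, all up (mitosis, Ras and MAPK output, hypoxia and glycolysis, neutrophil, macrophage, immediate-early). None was called with an estimated correlation (lowest adjusted p = 0.434) or by fry (lowest adjusted p = 0.299), and only the Ras list passed fry's mixed test (adjusted p = 0.00102). With each array left out in turn, the 3 Ras genes passed over the list alone every time. None of the 2 neutrophil, 2 mitosis and 2 immediate-early genes did so, nor did Mmp13 or Adam8. The count of mitosis genes that rose was 20 without p53-/- tumor 1 (median 0.43), 6 without p53R172H/+ tumor 2, and 0 without p53-/- tumors 2 or 3, p53R172H/+ tumors 1 or 3, or p53R172H/- tumor 3. The call of the immediate-early genes was lost without p53-/- tumor 1 (adjusted p = 0.0657), p53-/- tumor 2 (0.157) or p53R172H/+ tumor 3 (0.0581), and that of the macrophage and monocyte genes without p53-/- tumor 2 (0.311) or p53R172H/+ tumor 3 (0.0524).

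**Figure D3:**
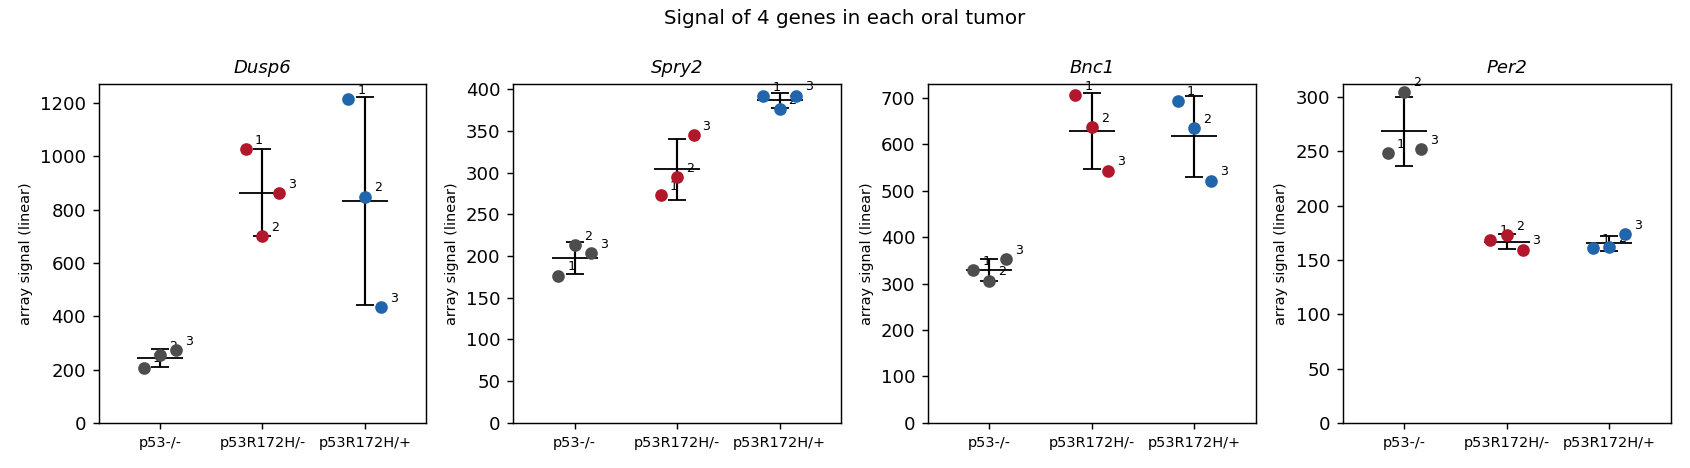
Array signal (linear units) of Dusp6, Spry2, Bnc1 and Per2 in each tumor, with the group mean and SD (n = 3) as dash and bar. Bnc1 is at 306 to 352 in p53-/- and at 522 to 706 in the mutant tumors, and Per2 at 248 to 305 and at 159 to 174, yet neither gene passed the adjusted threshold.

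The comparison of p53R172H/- with p53R172H/+ tumors asks what differs with the second allele of the labelled genotype, null or wild type. Of 19 measured fibroblast and matrix genes, 12 fell in the p53R172H/- tumors when adjusted over the list alone, 0 over all genes, with a list median of -0.65 (adjusted p = 0.561 with an estimated correlation). Col5a1, a fibrillar collagen gene, fell 2.09-fold (-1.07 ± 0.22 SE), from 1331 ± 341 to 623 ± 79.1 signal units (SD, n = 3 each). Sparc, a matrix glycoprotein gene, fell 1.40-fold (-0.48 ± 0.12 SE), Col5a2 1.89-fold (-0.92 ± 0.23 SE) and Col6a2 1.68-fold (-0.75 ± 0.19 SE). Col11a1, a minor fibrillar collagen gene outside the list, had the smallest p of all genes (2.34-fold lower, -1.23 ± 0.17 SE, adjusted p = 0.452). None of the 12 fibroblast and matrix genes passed over the list alone without p53R172H/+ tumor 2, where Col5a1 was at -0.92.

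Of 35 mitosis genes, 33 were higher on average in p53R172H/- tumors, but none passed over the list alone. The list median was 0.27 (adjusted p = 0.561 with an estimated correlation), 0.17 without p53R172H/- tumor 1 and 0.18 without p53R172H/+ tumor 2. Mki67 was at 0.50 ± 0.15 (SE), Top2a, a DNA topoisomerase, at 0.45 ± 0.14 (SE) and Ccnb2 at 0.43 ± 0.15 (SE). Of 32 p53 target genes, 28 were lower on average and none passed over the list alone (median -0.12, and -0.08 without p53R172H/- tumor 1, adjusted p = 0.561 with an estimated correlation). Plk3, a stress-responsive kinase, was at -0.53 ± 0.14 (SE), Zmat3, an RNA-binding protein gene, at -0.41 ± 0.13 (SE), Cdkn1a at -0.22 ± 0.10 (SE), with its other probe set at 0.04, Mdm2 at -0.13 ± 0.12 (SE), Ccng1 at -0.19 ± 0.18 (SE) and Ccnd1 at -0.05 ± 0.20 (SE). With 1 array left out, Mdm2 ran from -0.24 to -0.04, Ccng1 from -0.31 to -0.05 and Ccnd1 from -0.23 to 0.11. In the mevalonate list, Cyp51 (1.36-fold, 0.45 ± 0.10 SE) and Idi1 (1.27-fold, 0.34 ± 0.09 SE) rose when adjusted over the list alone out of 17, with a list median of 0.06 (adjusted p = 0.561 with an estimated correlation), 0.13 without p53R172H/- tumor 1, 0.04 without p53R172H/- tumor 3 and 0.10 without p53R172H/+ tumor 2. Neither gene passed over the list alone without p53-/- tumor 2, p53R172H/- tumors 1 or 3 or p53R172H/+ tumors 1 or 3, where Cyp51 was at 0.40 to 0.47. NRF2 targets had a median of -0.19 (adjusted p = 0.561 with an estimated correlation), -0.10 without p53R172H/- tumor 2 and -0.08 without p53R172H/+ tumor 2. No member passed, and Hmox1, heme oxygenase 1, was at -0.63 ± 0.18 (SE). EMT and mesenchymal genes had a median of -0.20 (adjusted p = 0.561 with an estimated correlation), beside the -0.65 of the fibroblast and matrix list. No member passed, and Lgals1 was at -0.45 ± 0.29 (SE). With the fibroblast and matrix list as a covariate the EMT median was 0.26 and Lgals1 was at 0.29, and without p53R172H/- tumor 1 the EMT median was -0.02 and Lgals1 was at -0.19. Muscle genes had a median of 1.94 (adjusted p = 0.561 with an estimated correlation) with no member passing. It was -0.68 without p53R172H/- tumors 2 and 3, which leaves 1 tumor in the group, 3.34 without p53R172H/- tumor 1, 0.86 without p53R172H/- tumor 2 and 1.29 without p53R172H/+ tumor 2.

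The higher genes with the smallest p were Glul, which encodes glutamine synthetase (1.78-fold, 0.83 ± 0.17 SE), the interferon-inducible gene Mndal (0.94 ± 0.19 SE), Hspb8, a small heat shock protein gene (0.57 ± 0.12 SE), C1galt1, an O-glycan transferase gene (0.77 ± 0.17 SE), and Eprs, a tRNA synthetase gene (0.30 ± 0.07 SE). The lower ones after Col11a1 were Lrrc20 (-0.50 ± 0.08 SE), Gpx7 (-0.65 ± 0.12 SE), Bloc1s2 (-0.61 ± 0.12 SE) and Nudt5 (-0.51 ± 0.10 SE, with another probe set at 0.01), and none passed. In all, 603 genes had an unadjusted p under 0.05 (limma), 243 higher and 360 lower, against 608 by chance, and the arrays did not overlap for 11.9% of genes, against 10% by chance.

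Camera with the preset correlation called 7 lists, 3 up (mitosis, muscle, mevalonate) and 4 down (fibroblast and matrix, p53 target, NRF2 target, EMT). None was called with an estimated correlation (lowest adjusted p = 0.561), by fry (lowest adjusted p = 0.495) or by fry's mixed test. The call of the p53 target genes was lost without p53R172H/- tumor 1 (adjusted p = 0.0592), that of the NRF2 target genes without p53R172H/- tumor 2 (0.172) or p53R172H/+ tumor 2 (0.162), and that of the mevalonate and cholesterol synthesis genes without p53R172H/- tumor 3 (0.131) or p53R172H/+ tumor 3 (0.0733). The call of the EMT regulators and mesenchymal genes was lost without p53-/- tumor 1 (0.0569), p53R172H/- tumor 1 (0.717), p53R172H/+ tumor 1 (0.130) or p53R172H/+ tumor 2 (0.158).

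**Figure D4:**
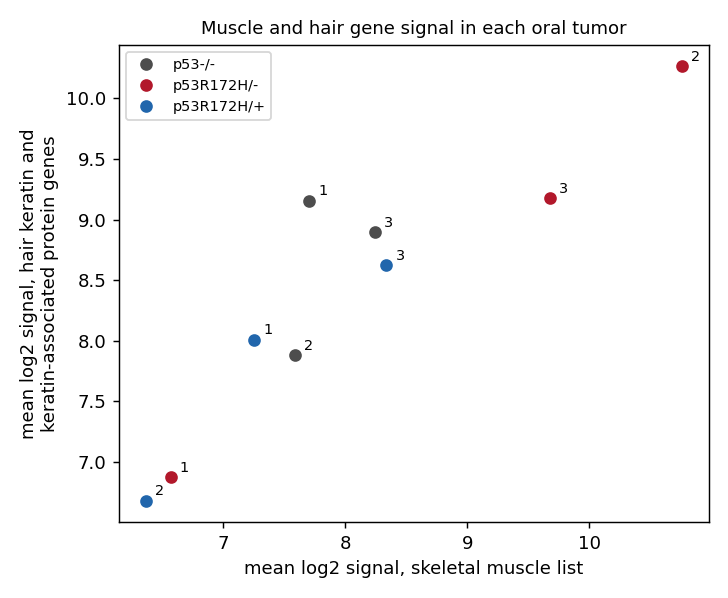
Mean log2 signal of the skeletal muscle list (horizontal) and of hair keratin and keratin-associated protein genes (vertical) in each of the 9 tumors, coloured by genotype and numbered by tumor. The p53R172H/- tumors span 6.57 to 10.76 for muscle, and p53R172H/+ tumor 2 has the lowest values of both lists (6.37 and 6.68).

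Both mutant groups together were set against the p53-/- tumors to ask what the 6 tumors with the mutant allele share. Of 35 mitosis genes, 21 rose when adjusted over the list alone, 0 over all genes, with a list median of 0.44 (adjusted p = 0.333 with an estimated correlation). Cdc20 rose 1.39-fold (0.48 ± 0.08 SE), Kif20a 1.75-fold (0.81 ± 0.14 SE), Nusap1 1.73-fold (0.79 ± 0.14 SE) and Ccnb2 1.64-fold (0.71 ± 0.13 SE). Of 16 Ras and MAPK output genes, 4 rose when adjusted over the list alone, 0 over all genes. The list's median was 0.36 (adjusted p = 0.333 with an estimated correlation), 0.23 without p53-/- tumor 1 and 0.24 without p53R172H/- tumor 1. The genes that rose were Spry2 (1.74-fold, 0.80 ± 0.10 SE), Dusp6 (3.34-fold, 1.74 ± 0.28 SE), Ier3 (1.40-fold, 0.48 ± 0.11 SE) and Dusp5 (1.28-fold, 0.35 ± 0.11 SE). Beside these lists, the mean of the 6 salivary gland genes was lower in every mutant tumor (8.14 to 8.34) than in every p53-/- tumor (8.35 to 8.50), without a call by camera (median -0.11, adjusted p = 0.356).

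Of 15 immediate-early genes, Ier2, Junb, Zfp36 and Fos rose when adjusted over the list alone, 0 over all genes, with a list median of 0.27 (adjusted p = 0.333 with an estimated correlation), 0.14 without p53-/- tumor 2, and Fos at 0.70 ± 0.21 (SE). None of these 4 genes passed over the list alone without p53-/- tumors 1 or 2, where Fos was at 0.43 and 0.75. Of 11 neutrophil genes Il1b rose when adjusted over the list alone (2.25-fold, 1.17 ± 0.31 SE), with a list median of 0.24 (adjusted p = 0.335 with an estimated correlation). Of these genes 8 were higher and 3 lower on average, and Cxcr2, a receptor for neutrophil chemokines, was at -0.31 ± 0.14 (SE), -0.49 without p53-/- tumor 1 and -0.18 without p53-/- tumor 3. Hypoxia and glycolysis genes had a median of 0.17 (adjusted p = 0.333 with an estimated correlation) with none passing over the list alone. Vegfa was at 0.51 ± 0.13 (SE) and Adm, the vasoactive peptide adrenomedullin, at 0.50 ± 0.15 (SE), or 0.30 without p53-/- tumor 2, with another probe set of Adm at -0.04. In lists that were not called, Myc, the proliferation-linked transcription factor (0.45 ± 0.09 SE), Chek2, a checkpoint kinase (0.47 ± 0.12 SE), Mmp13 (2.07 ± 0.49 SE, 1.29 without p53-/- tumor 2), Adam8 (0.90 ± 0.19 SE), Mmp10 (0.81 ± 0.24 SE) and Sc5d (0.59 ± 0.14 SE) rose, and Dcxr (-0.66 ± 0.14 SE), L1cam (-0.35 ± 0.10 SE) and Sox10 (-0.31 ± 0.11 SE) fell, each adjusted over its list alone. The basal keratinocyte list, with a median of 0.06, and the differentiated squamous list, with a median of -0.03 but a mean of 0.05 and a test that points up, were not called. Other lists without a call included macrophages (median 0.23, adjusted p = 0.0529), fibroblast and matrix (-0.19), muscle (0.37), endothelium (-0.01), T and NK cells (-0.09) and type I interferon response (-0.03, mean 0.05). Among genes fixed in advance, Cdkn1a was at -0.10 ± 0.08 (SE), with its other probe set at 0.50, Mdm2 at 0.09 ± 0.10 (SE), Ccng1 at -0.36 ± 0.15 (SE, another probe set at 0.04), Ccnd1 at -0.21 ± 0.17 (SE) and Mki67 at 0.28 ± 0.13 (SE). With 1 array left out, Cdkn1a ran from -0.20 to -0.03, Mdm2 from 0.06 to 0.15, Ccng1 from -0.45 to -0.19, Ccnd1 from -0.30 to -0.12 and Mki67 from 0.13 to 0.46.

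In this comparison 1938 genes had an unadjusted p under 0.05, 832 higher and 1106 lower, and the smallest adjusted p was 0.152 (limma), shared by Spry2 and Bnc1 (1.88-fold, 0.91 ± 0.12 SE). The arrays did not overlap for 7.27% of genes, against 2.38% by chance. The other higher genes with the smallest p were Pclaf (0.57 ± 0.09 SE), Dusp6 and Mta2 (0.45 ± 0.07 SE), and the lower ones were Per2 (1.61-fold, -0.69 ± 0.09 SE), Prrc1 (-0.45 ± 0.07 SE), Cpt1c (-0.68 ± 0.11 SE), Kdm5c (-0.70 ± 0.12 SE) and Drap1 (-0.45 ± 0.08 SE). Of 5 other probe sets of Kdm5c, 2 had the opposite sign. Camera with the preset correlation called 5 lists, all up (mitosis, hypoxia and glycolysis, Ras and MAPK output, immediate-early, neutrophil). None was called with an estimated correlation (lowest adjusted p = 0.333) or by fry (lowest adjusted p = 0.0782), and 7 passed fry's mixed test. In exact permutation tests of each array's list mean (two-sided), 6 lists had p under 0.05, with p = 0.0238 for the Ras list (up) and the salivary gland list (down), the smallest value the design allows, and p = 0.0476 for mitosis. None passed after adjustment (lowest adjusted p = 0.222), for which 14 lists at the smallest p would be needed. With each array left out in turn, 8 of the 21 mitosis genes, 3 of the 4 Ras genes (Spry2, Dusp6 and Ier3), Mmp13 and Adam8 passed over their list alone every time. None of the other genes said above to have risen or fallen did so. The call of the neutrophil genes was lost without p53-/- tumor 2 (adjusted p = 0.0743) or 3 (adjusted p = 0.0922), 8 mitosis genes rose without p53-/- tumor 3, and without p53R172H/+ tumor 3 Dusp6 passed over all genes (1.94, adjusted p = 0.0375).

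The fold changes of the mutant groups against p53-/- share the same 3 control arrays. Their Pearson's r across genes was 0.628, against a mean of 0.447 (95% range -0.49 to 0.96) in 100 simulations of unchanged groups, and their covariance was 0.0421 against 0.0231 (-0.0206 to 0.0879). The sign agreed for 76.9% of genes, against 66.5% simulated (37.0 to 90.0%). All 3 values lay inside the simulated ranges of unchanged groups. These ranges are wide, so the values can neither show nor exclude a shared effect beyond the shared controls. Of genes with an unadjusted p under 0.05, 314 were higher and 344 lower in both comparisons, where independent lists, which leave out the shared controls, would share 37.2 and 62.4. With 3 controls the control group cannot be divided into parts that each keep a pair of arrays, so part of the excess may come from the shared controls.

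The 3' to 5' ratio of the Gapdh control probe sets, a sign of RNA integrity, was -0.11 to 0.05 on the log2 scale over the arrays. That of beta-actin was 0.53 ± 0.10 (SD, n = 6) in mutant and 0.69 ± 0.09 (SD, n = 3) in p53-/- tumors, a difference of -0.16 with an exact permutation p of 0.0476 and an adjusted p of 0.381.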

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

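Alternatives chosen after the data were seen were the fibroblast and hair lists as covariates, leaving out pairs of arrays, pooling the mutant arrays as 1 group, the exact permutation of list means, the calls of list members with each array left out, and camera without a variance trend. Log2 signals rest on 3 arrays per group, and signals near the floor understate changes. Counts of genes called (limma, adjusted p under 0.05) were 0 under every alternative run, except as follows. With the muscle list as a covariate 63 genes were called for p53R172H/- against p53-/- and 4 for both mutant groups. With the fibroblast list as a covariate there were 2, 1 (p53R172H/- against p53R172H/+) and 6 (both). Without p53R172H/- tumors 2 and 3 there were 3 (p53R172H/- against p53-/-), but these rest on 1 tumor, which is assumed to vary like the other groups. The leave-one-out range was 0 to 1 for both mutant groups. The cause was not tested.

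With an estimated correlation and by fry 0 lists were called in each of the 4 comparisons. Exact permutation also gave 0, but this says nothing of stability, since 3 tumors against 3 cannot pass and 6 against 3 would need 14 of 28 lists at the smallest p. For p53R172H/+ against p53-/- the hair covariate gave 10 lists, and leaving out arrays gave 4 to 10. For both mutant groups the mean of all probe sets gave 9, array weights 8, the Gapdh ratio as a covariate 8, the fibroblast covariate 8, the hair covariate 9 and the set without p53R172H/- tumors 2 and 3 9, and leaving out arrays gave 5 to 9. Here too the cause was not tested. The median of the mitosis list for p53R172H/- against p53-/- kept its direction in all settings, 0.44 to 0.75.

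The tumor number of the labels as a replicate block called 0 genes in each comparison, but the numbers do not pair the tumors. Only 4 of 9 same-number pairs had deviations with r over 0.1 (-0.50 to 0.24), and 2 of 9 arrays correlated best with an array of their own number.

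For p53R172H/- against p53-/-, Cdkn1a was at 0.16 with the mean of probe sets, and Mdm2 at -0.00376 with the Gapdh covariate, -0.032 without p53R172H/- tumor 1 and -0.00683 without tumor 3. Without p53R172H/- tumors 2 and 3, Ccnd1 was at 0.11, Myh4 at -1.21, Eno3 at -0.86, Ckm at -0.84, the NRF2 list at -0.0744 (its test turned up) and the muscle list at -1.21. For p53R172H/+ against p53-/-, Mki67 was at -0.015 with array weights and without p53R172H/+ tumor 1, -0.045 with the Gapdh covariate, -0.012 with the fibroblast covariate and -0.12 without p53-/- tumor 2 (with or without p53R172H/- tumor 2). Cdkn1a was at -0.036 with the Gapdh covariate, -0.013 with the hair covariate, -0.0907 without p53-/- tumor 1 and -0.0184 without p53R172H/+ tumor 1. With each array left out in turn Cdkn1a ran from -0.0907 to 0.0814 and Mki67 from -0.12 to 0.207. For p53R172H/- against p53R172H/+, Mdm2 was at 0.00285 and Ccnd1 at 0.24 with the muscle covariate, Ccnd1 at 0.16 with the hair covariate, and Lgals1 at 0.29, Tgfb3 at 0.0756 and the EMT list at 0.26 with the fibroblast covariate. Without p53R172H/- tumors 2 and 3 Ccnd1 was at 0.29, Gclm 0.0148, Snai2 0.0338, Myh4 -0.66, Ckm -0.47, Tnni2 -0.53, the NRF2 list -0.00503 (its test turned up) and the muscle list -0.68. Ccnd1 was at 0.085 without p53R172H/- tumor 2 (with or without p53-/- tumor 2) and 0.106 without p53R172H/+ tumor 2, with a leave-one-out range of -0.233 to 0.106. For both mutant groups Cdkn1a was at 0.20 with the mean of probe sets. Testing only the groups compared gives the same fit for both mutant groups, and testing every probe set gives no list values. The cause of these reversals was not tested.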

Other observations

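The tests of basal epithelium, of muscle fibres, of muscle and hair together and of the interval around the muscle and RNA ratio correlation were chosen only after the results were seen, and so were the genes and lists named in this paragraph and the next. Of the 100 genes that varied most within groups, 29 were hair keratin or keratin-associated protein genes, 15 were muscle genes, 2 were CXCR2 ligand genes and 54 were others, the chitinase-like gene Chil4 and the lactoferrin gene Ltf with the largest variation. The hair follicle keratin gene Krt27 was at 3862 signal units in p53R172H/- tumor 2, 202 in p53R172H/- tumor 1 and 154 in p53R172H/+ tumor 2, and the keratin-associated protein gene Krtap8-1 at 5739, 223 and 159. Acta1, skeletal alpha-actin, was at 7605, 273 and 149 in the same tumors. Alas2, an enzyme of heme synthesis in red cell precursors, was at 2516 in p53R172H/- tumor 2 and at 43.3 to 163 in the other tumors.

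Genes of chemokines that attract neutrophils also differed between tumors. Ppbp was at 496 to 4275 signal units in p53-/-, 3357 to 12499 in p53R172H/- and 940 to 8781 in p53R172H/+ tumors, so the groups overlapped. Cxcl5 was at 143 to 1431, 834 to 3742 and 231 to 3696 in these groups, Odam, a secreted epithelial protein, at 91.8 to 846, 510 to 3645 and 49.6 to 3575, and Dynap at 279 to 1095, 2035 to 8039 and 820 to 5762. All 4 genes were highest in p53R172H/- tumor 1 and p53R172H/+ tumor 2. The mean log2 signal of 6 CXCR2 ligand genes was 1.27 higher in mutant than in p53-/- tumors (exact permutation p = 0.0952, two-sided). With the hair list as a covariate no gene was called for p53R172H/- against p53-/- tumors. With the muscle list as a covariate, 63 genes were called for this comparison, 30 higher and 33 lower. Their adjusted p was 0.0194 to 0.0493 (limma), and many were at 0.0493, close to the threshold. All 63 had the same sign without the muscle covariate. They included Dynap (3.45 ± 0.48 SE), Dusp6 (2.02 ± 0.31 SE), the EGF receptor ligand gene Hbegf (0.95 ± 0.12 SE) and, among lower genes, the cornified envelope genes Lce1b (-0.84 ± 0.09 SE) and Lce1l (-1.50 ± 0.20 SE).

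Of 35 mitosis genes, 32 were higher on average in p53R172H/- than in p53-/- tumors (adjusted p = 0.361 with an estimated correlation), and 3 technical explanations were tested. After quantile normalization the list's median stayed 0.609 above that of all genes, which argues against scaling as the whole cause. With muscle, matrix or hair content as a covariate the list's median was at least 0.587. The slopes of these fits rest only on the few tumors within each group, so they cannot decide on these contents. The basal keratinocyte list moved by 0.0455 (plus 2 standard errors, 0.175), below the 0.464 that the mitosis list reaches less 2 standard errors. These standard errors are over the 16 and 35 genes of the lists and leave out the spread between tumors. Over tumors, the mean log2 signal of the basal list was 10.22 ± 0.02 in p53-/- and 10.24 ± 0.03 in p53R172H/- tumors (SD, n = 3 each). These values argue against a larger share of basal epithelium as the whole cause. A difference in proliferation between the genotypes may remain, as a hypothesis, and so may a difference in muscle, matrix or hair content. Differences in salivary gland content and in RNA integrity by the beta-actin ratio were not weighed and may remain as well. That log2 ratio was 0.54 in p53R172H/- and 0.69 in p53-/- tumors. In 2 of the 84 splits of the 9 tumors into 6 and 3, the real one included, was the mitosis difference as large in size as for both mutant groups (0.412, highest other 0.435). The exact permutation test, which doubles the share of 1 side, gave p = 0.0476. Of 100 simulated sets with no group effect 0 had as large a list median. As 1 of 28 lists the mitosis list did not pass (adjusted p = 0.0782 by fry, 0.333 with an estimated correlation), so chance cannot be excluded.

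For the muscle genes, sampling and RNA quality were weighed as technical explanations and no biological explanation was tested. In p53R172H/- tumor 2, 16 of 19 were higher by over 1 on the log2 scale than in tumor 1 (median difference 4.55). In tumor 3 the count was also 16 (median difference 3.52). The count for tumor 2 fell short of a cut of 17, which was set only after the results were seen. By this count muscle fibres in the sampled tissue cannot be told apart from other sources. The muscle list and the Gapdh 3' to 5' ratio had r = 0.405 (permutation p = 0.286, rho = 0.400, p = 0.293, 0.145 without the 2 farthest tumors), with a 95% interval of -0.355 to 0.842, and the beta-actin ratio had r = 0.283 (-0.469 to 0.797). Degradation would have needed r under -0.6, below both intervals over the 9 tumors. No interval was taken without the 2 farthest tumors, and the interval rule was set after r was seen. The test therefore argues only weakly against degradation as the whole cause. Muscle and hair lists moved together over the 9 tumors (r = 0.910, permutation p = 0.00065, rho = 0.917, p = 0.00155), also as deviations from group means (r = 0.947, permutation p = 0.0136, rho = 0.900, p = 0.0178, 0.841 without the 2 farthest), and the adjusted permutation p over the 3 relations was 0.00195 and 0.0204. A candidate explanation is that adjoining haired skin and muscle were sampled together in varying amounts.

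Of 16 Ras and MAPK output genes, 13 were higher on average in both mutant groups together than in p53-/- tumors (adjusted p = 0.333 with an estimated correlation). With the immediate-early list as a covariate the Ras list's median was 0.327. This fit cannot decide on handling, because its slope rests only on the few tumors within each group. In each mutant group the tumor with the highest Ras mean had the lowest immediate-early mean, while in p53-/- the same tumor was highest in both. With muscle, matrix or hair content as a covariate the Ras list's median was at least 0.279. The slopes of these fits have the same limit, so they cannot decide on these contents either. A difference between genotypes in this output may remain, as a hypothesis that was not tested further. A response to handling may remain too, and so may a difference in muscle, matrix or hair content. Differences in salivary gland content and in RNA integrity by the beta-actin ratio were not weighed and may remain as well. That log2 ratio was 0.53 in mutant and 0.69 in p53-/- tumors.

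Other splits of the tumors gave mixed results. For both mutant groups against p53-/-, 4 of 84 splits had as many genes at an unadjusted p under 0.05 (1980 with 2 groups in the model, highest other 2605). The splits with 2605 and 2376 genes both set p53R172H/+ tumor 3 apart together with 2 p53-/- tumors. In 9 of 100 simulated sets with no group effect there were as many as the 1938 of the model with 3 groups, so chance cannot be excluded for this count. Of the 84 splits 62 called as many lists (5, highest other 12), so chance cannot be excluded for their number. Of the other splits 8 called genes, against 0 in the real one, with 41 genes in 1 split and 1 to 7 in the others. The split with 41 set apart p53-/- tumor 2, p53R172H/- tumor 1 and p53R172H/+ tumor 2. These had the lowest means of the hair list (7.88, 6.88 and 6.68, against 8.01 to 10.26), which points to a structure of the samples. Each also had the highest mean log2 signal of the CXCR2 ligand genes within its group (9.62, 10.85 and 10.88). What else these tumors share was not tested. With 10 splits of 6 tumors no share under 0.05 can be had. For p53R172H/- against p53-/- 1 of 10 splits had as many genes (1897, highest other 896) and 3 as many lists (10, highest other 11). In the simulations with no group effect 4 of 100 sets had as many genes in that comparison, with a median of 248.5. For p53R172H/+ against p53-/- the splits with as many genes and lists were 3 (1259, highest other 1509) and 4 (6, highest other 7). Both larger gene counts there (1316 and 1509) came from splits with p53R172H/+ tumor 3 on the side of 2 p53-/- tumors. What this tumor shares with them was not tested. For p53R172H/- against p53R172H/+ these were 3 (603, highest other 1224) and 4 (7, highest other 14).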
